A study of Mus musculus with 6 samples.

How the data were processed

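Single cells were made from the lungs of female C57BL/6J mice at days 0, 3, 7, 10, 14 and 21 after 1 oropharyngeal dose of bleomycin. Per the labels' protocols, the dose was 2 mg/kg in 50 µL, lungs were digested with Liberase for 60 min, cells were enriched on a Percoll gradient and stained with Calcein AM, and 15000 cells were loaded for capture on the BD Rhapsody system. Libraries were made with the TAS-Seq method and sequenced on an Illumina NovaSeq instrument. The number of mice and whether lungs were pooled are not given in the sources used here. There was 1 library per day, so day, library and batch are the same thing.

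The deposited values are a count per gene and cell, and the authors made them from the reads before depositing them. The submitters' processing notes name cutadapt 3.4, Bowtie2 2.4.2, R 4.1.3 and the GRCm38 genome. The deposited counts look like reads that were not collapsed to molecules, and they are called reads here; whether molecular identifiers were used is not given in the sources used here. This is inferred from genes of few cells, in which 52.0% to 56.4% of the values above 0 were single reads and 24.4% to 28.9% were 5 or more. In genes seen in under 3% of cells and at least 20 cells, the median of the values of at least 5 reads was taken as the reads per molecule, which gave 15, 13, 12, 11, 14 and 14 at days 0, 3, 7, 10, 14 and 21. Intervals on gene ratios were therefore made on molecule equivalents, which are reads divided by this number, a choice made after seeing the data. They cover counting error only and not the spread between mice.

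All 6 matrices were joined over 41169 genes. Per the deposited files there were 4001, 4904, 4051, 5146, 6376 and 6746 cells, with medians of 2670, 2984, 3125, 3367, 3018 and 2671 genes per cell. Cells with under 200 genes (6 cells) or over 25% mitochondrial reads (409 cells) were left out. Scrublet scores, as implemented in scanpy, removed 986 doublets: the automatic threshold was used at days 0, 7 and 21, and the highest 5% of scores at days 3, 10 and 14, where the automatic threshold marked under 0.5% (0.0617%, 0.0785% and 0%). This left 3901, 4616, 3928, 4838, 5978 and 6568 cells. Clustering used 2000 variable genes, 40 principal components, 15 neighbours and Leiden resolution 1.5 with seed 0, without batch correction, and gave 56 clusters. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.

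Clusters were named from markers of 32 classes that were fixed before the data were examined, of which 2 markers were not in the files. The rule that turns markers into names was settled after looking at the clusters. A first version used markers among the 50 top genes of a cluster and left clusters 31, 45 and 48 without a name. A second used the share of enriched markers and put arterial or venous endothelium, type 1 dendritic cells and plasma cells in the wrong class. The version used combines these, asks for at least 3 markers, and has ratios of 0.6, 0.5 and 1.25 that were chosen on these clusters. Clusters 28, 30, 35 and 51 stayed without a name.

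Shares have exact binomial intervals. For each class with at least 50 cells at a day, reads were summed over cells and divided by their total to give CPM (reads of a gene per 1e6 reads of the class). Ratios are to day 0, or to day 3 for classes with under 50 cells at day 0, a choice made after seeing the data. For a gene without reads in a group only levels are given. For 18 gene lists, the median log2 ratio of members with at least 3 counts was taken with a pseudocount of 5 CPM, with an interval from 1000 draws and a percentile among 10000 random lists matched in 20 expression bins. The lists were cell cycle, interferon response, p53 targets, MHC class II, inflammatory cytokines, dissociation stress, extracellular matrix, contractile, resting alveolar fibroblast, stromal acute phase, alternative activation, lipid-associated macrophage, resident alveolar macrophage, surfactant, transitional epithelium, endothelial activation, T cell effector and regulatory T cell genes. Cycling cells and 60 ligand-receptor pairs were counted after thinning every cell to 2000 reads, with detection in at least 10% of cells. No test was made, since no group has a replicate. The naming rule with its ratios, the day 3 reference and the molecule equivalents were chosen after seeing the data. Gene lists, pairs and the other thresholds and main settings were chosen before the data were examined.

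Named genes were, for each class and day of the main comparisons, the 4 highest and 2 lowest ratios among genes with at least 30 counts, at least 20 CPM, at least 10% of the level of the highest class and an interval beyond 2-fold. Not every such gene is named in the text. Ftl2-ps and Bambi-ps1 met the rule, but they are pseudogenes that share reads with their parent genes and were passed over. The other genes named, mostly list members, were chosen after their values were seen. On simulated data made from the fibroblasts of days 21 and 0, true log2 ratios of 2, -2, 1 and -1 came out as 1.90, -1.56, 0.89 and -0.84, and the intervals held the truth for 92%, 92%, 86% and 84% of genes and for 89.0% of unchanged genes, so the intervals were too narrow there. The simulation took the reads per molecule as known, had no differences between cells and left out genes with few reads at day 0. How much too narrow the intervals on the real data are was therefore not measured. Alternatives to the clustering, doublet removal, filters, scaling, pseudocount, thinning and detection were run, 9 of which were added after seeing the data.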

Results

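Lung cells of female C57BL/6J mice were profiled by single-cell RNA sequencing over the weeks after a single dose of bleomycin, a DNA-damaging drug that brings about lung fibrosis in rodents. The dose was 2 mg/kg in 50 µL, given by oropharyngeal aspiration. The submitters asked how the network of signals between lung cells differs over the start and progression of fibrosis. There were 6 libraries, 1 for each of days 0, 3, 7, 10, 14 and 21, and day 0 served as the reference. The files held 31224 cells, of which 4001, 4904, 4051, 5146, 6376 and 6746 came from days 0, 3, 7, 10, 14 and 21. Total reads per library were 294982871, 390013435, 359913346, 402271130, 567603988 and 605977791 in the same order, and the median cell had 47960 to 50573 reads at each day. With 1 library per day there was no replicate and no test, and a difference between days is a difference between libraries. Intervals in parentheses are 95% intervals that cover counting error only.

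After filtering, 29829 cells formed 56 clusters, which were named from fixed marker genes. A class name below stands for cells that resemble that type by its markers (fibroblast-like, macrophage-like and so on). Shares are of retained cells and can be set by the enzymatic digestion, the density gradient and the viability dye as well as by the tissue. Doublet removal took 1.29%, 5.00%, 1.21%, 5.01%, 5.01% and 1.11% of the cells at days 0, 3, 7, 10, 14 and 21.

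The first comparison concerned the cellular make-up of the lung. Immune cells made up 25.0% (23.6 to 26.4) of the day 0 library, 60.7% (59.2 to 62.2) at day 7 and 48.2% (46.9 to 49.4) at day 21. Epithelial cells were 21.0% (19.7 to 22.3) at day 0, 3.84% (3.27 to 4.49) at day 7 and 5.38% (4.84 to 5.95) at day 21. Endothelial cells were 23.8%, 13.5% and 26.2% at those days, and mesenchymal cells 25.9%, 15.8% and 18.5%. A larger immune share lowers every other share, so the main classes are also given below as shares of their own compartment.

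In the epithelium, AT2 cells, which make surfactant, were 12.4% (11.4 to 13.5) of cells at day 0 and 0.611% (0.392 to 0.908, 24 cells) at day 7. They were 1.57% at day 10, 2.54% at day 14 and 2.41% (2.05 to 2.81) at day 21. AT1 cells, the flat cells of gas exchange, were 6.23% (5.49 to 7.03) at day 0, 0.433% (0.252 to 0.692, 17 cells) at day 7 and 1.22% at day 21. These AT1 shares depended on the filters: they were 5.85%, 0.229% and 0.640% with at least 500 genes per cell, and 2.48%, 0.132% and 0.174% with the highest 5% of doublet scores removed in every library. Cells with the keratin-rich markers of the transitional state between AT2 and AT1 were 2 cells at day 0, 0.0513% (0.00621 to 0.185) of the library, and 1.88% (1.48 to 2.36) at day 7. The day 0 share was 0.456% without doublet removal and 0.436% with at least 500 genes per cell. Within the epithelium alone, the transitional share was 0.244% at day 0, 14.1% at day 3, 49.01% at day 7 and 13.9% at day 21, while AT2 cells were 59.1%, 49.03%, 15.9% and 44.8% and AT1 cells 29.7%, 24.8%, 11.3% and 22.7%.

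Macrophages and monocytes differed in their timing. Classical monocytes, the blood cells recruited through Ccr2, were 1.10% (0.799 to 1.48) at day 0 and highest at day 3 with 7.91% (7.14 to 8.72). Interstitial or monocyte-derived macrophages were 0.743% (0.498 to 1.07) at day 0, 2.58% at day 3, 15.5% (14.4 to 16.7) at day 7 and 6.56% (5.97 to 7.19) at day 21. The class named alveolar macrophages, which pools 2 clusters described below, was 4.23% (3.62 to 4.91) at day 0, lowest at day 3 with 1.52% (1.18 to 1.91), and 8.53% (7.86 to 9.23) at day 21. Of immune cells alone, alveolar macrophages were 16.9% (14.6 to 19.4) at day 0, 3.27% at day 3 and 17.7% (16.4 to 19.1) at day 21, so the higher day 21 share of the library was not seen on this scale. Classical monocytes were 4.41% of immune cells at day 0 and 17.0% at day 3, and interstitial or monocyte-derived macrophages 2.98%, 5.56%, 25.5% and 13.6% at days 0, 3, 7 and 21. The clusters that held most alveolar macrophages were not the same over time: cluster 34 held 93.9% of them at day 0 and 61.4% at day 3, and cluster 6 held 81.2% at day 7 and 95.2% at day 21. Cluster 34, with Krt79, Fabp1, Marco and Siglecf among its top genes, had 155 cells at day 0 and 27 at day 21. Cluster 6, with Chil3, Plet1 and Atp6v0d2 among its top genes, had 10 and 533. The day 21 share of the class was therefore not a return of the cluster that led at day 0. Type 2 conventional dendritic cells were 0.436% at day 0 (0.692% with the class set per cell from markers) and 2.77% at day 7, and migratory dendritic cells 0.128% and 1.43%.

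T cells were 4.54% (3.91 to 5.24) at day 0 and 11.9% (11.1 to 12.8) at day 14, and B cells 8.84% (7.97 to 9.78) and 18.4% (17.4 to 19.4). Of immune cells alone, T cells were 18.2% (15.8 to 20.7) and 22.7% (21.3 to 24.2), and B cells 35.4% (32.4 to 38.5) and 35.1% (33.5 to 36.8), so the larger B cell share went with the larger immune share. Plasma cells, the antibody-secreting cells, were 1 to 3 cells in each library up to day 14 and 41 cells, or 0.624% (0.448 to 0.846), at day 21. With the class set per cell from markers they were 0.205% at day 0, 0.537% at day 10 and 0.959% at day 21. Neutrophils followed no order in time, with 2.57% at day 7, 0.661% at day 10, 2.76% at day 14 and 0.213% at day 21. General capillary endothelium was 15.5% (14.4 to 16.7) at day 0, 7.13% (6.34 to 7.98) at day 7 and 18.3% (17.4 to 19.3) at day 21, and lymphatic endothelium was 0.564% at day 0 and 1.61% at day 21. Of the endothelium alone, general capillary cells were 65.1%, 52.8% and 69.9% at days 0, 7 and 21, and lymphatic cells 2.37%, 5.66% and 6.15%. Fibroblasts were 18.7% (17.5 to 19.9) at day 0 and 12.8% (11.7 to 13.9) at day 7. Among mesenchymal cells of the named classes, which leave out cluster 28 with its pericyte markers, they were 72.2% and 81.0% at those days. Clusters left without a name by thresholds set on these data held 4.15%, 2.56%, 5.98%, 5.25%, 1.82% and 1.71% of the cells at days 0, 3, 7, 10, 14 and 21.

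**Figure D1:**
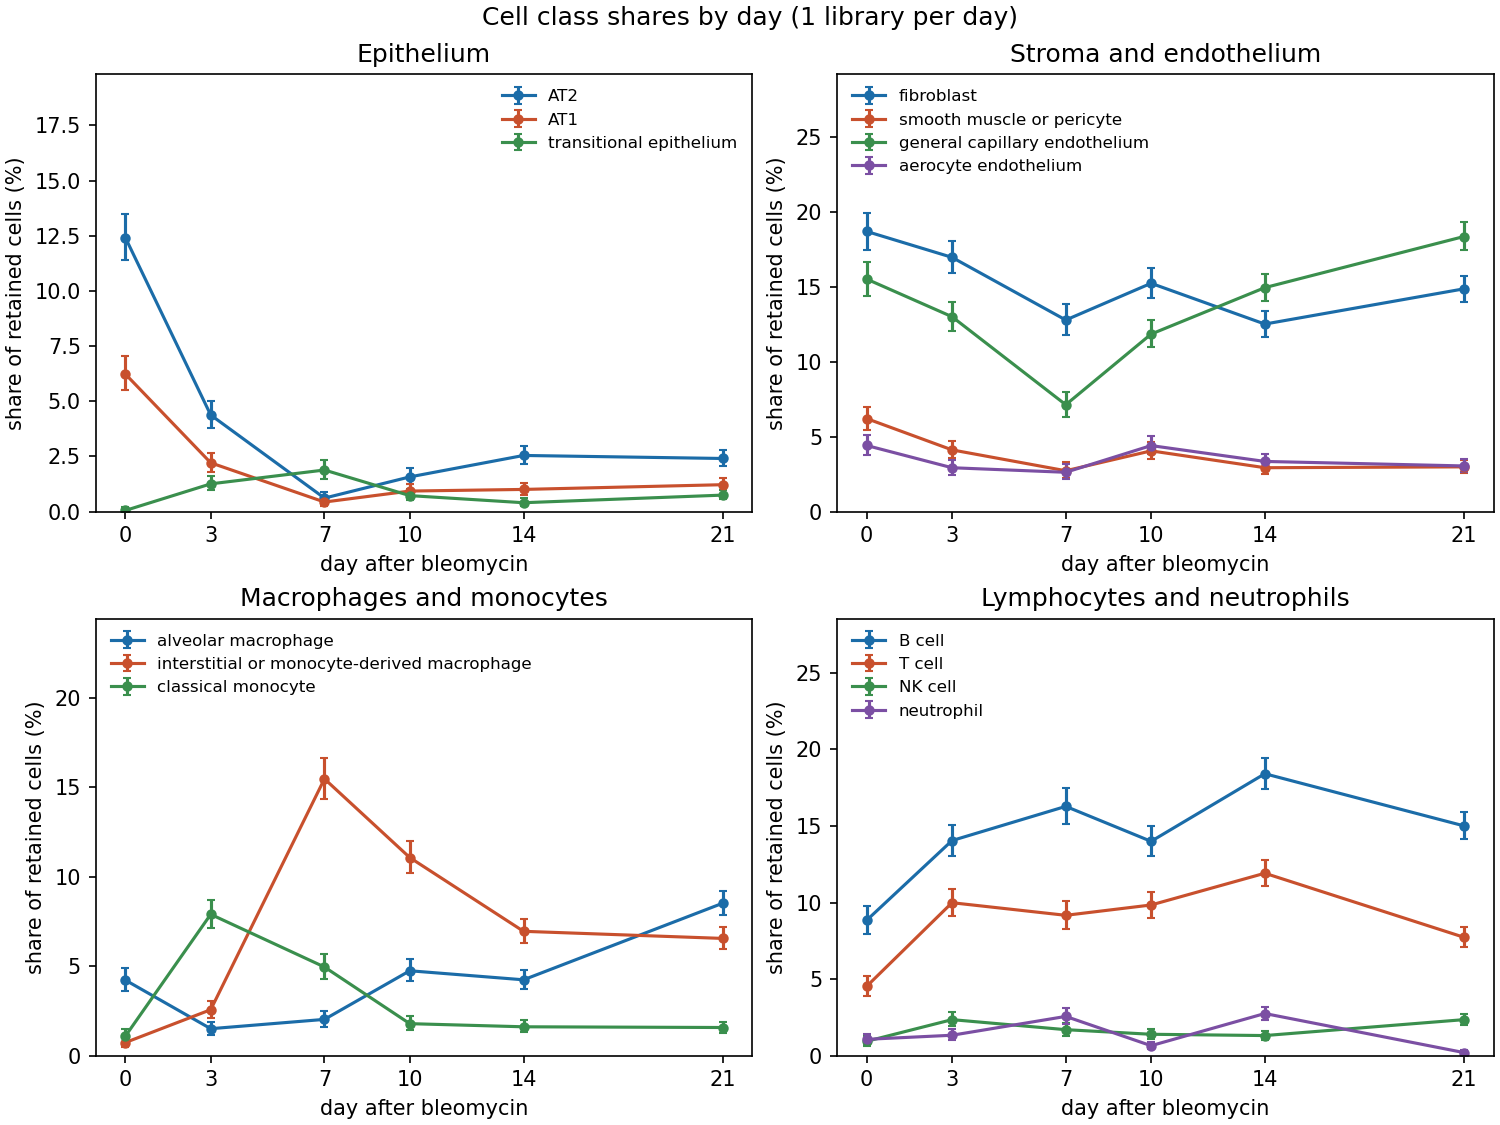
Share of retained cells (%) of 14 cell classes against the day after bleomycin, in 4 panels, with 1 library per day and bars for the exact 95% binomial interval, which covers counting error only. AT2 and AT1 shares are lowest at day 7, classical monocytes are highest at day 3, and interstitial or monocyte-derived macrophages are highest at day 7 with 15.5%.

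The fibroblast pool had higher inflammatory genes at day 3, and higher matrix genes from day 7 on than at day 3. At day 3, Saa3, an acute phase protein, was 7938 CPM against 6.54 CPM at day 0, 1214-fold (825 to 1954) higher. Cxcl13, a chemokine that attracts B cells, had no read at day 0 and 1891 CPM at day 3, and Lcn2, an iron-scavenging acute phase protein, was 163-fold (109 to 254) higher. From day 7 on, Spp1, the matrix protein and cytokine osteopontin, was among the genes with the largest ratio: 8.12 CPM at day 0, 5026 CPM at day 7 and 5449 CPM at day 21, the latter 671-fold (469 to 1007) higher. At day 0, B cells, which should lack these genes, had 5.498 CPM of Saa3, 2.75 CPM of Lcn2 and 4.99 CPM of Spp1, and 66.3 CPM of Saa3 at day 3, so the day 0 levels of fibroblasts were not separated from free RNA and the ratios depend on it. The fibroblast pool came from different clusters at different days, with 51.9% of it in cluster 22 at day 0, 34.5% in cluster 31 at day 3, and 24.1%, 40.4%, 50.3% and 47.0% in cluster 3 at days 7, 10, 14 and 21. Cluster 17, with Grem1, Thbs4, Cthrc1, Tnc and Timp1 among its top genes, had 1 cell at day 0 and 108 (21.5% of the pool) at day 7. Cluster 22, with Igfbp3, Inmt, Slc7a10, Npnt and Colq among its top genes, had 378 and 3. Several genes named below are thus top genes of clusters whose size differed by day. A different mix of fibroblasts was therefore not separated from a difference within them.

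Across the 14 genes of the acute phase and stromal chemokine list, the median log2 ratio to day 0 was 2.11 (1.95 to 2.26) at day 3, 1.48 at day 7, 1.16 at day 10, 0.37 at day 14 and 0.47 at day 21. At day 3, 13 of the 14 were at least 2-fold higher, counting ratios with a pseudocount. Il33, an alarmin, was 34.9 CPM at day 0 and 240 CPM at day 3, and Il6, an inflammatory cytokine, 318 CPM and 716 CPM, with 119 CPM at day 21. Cxcl12, a ligand for Cxcr4 on leukocytes, was 275 CPM at day 0 and 898 CPM at day 7. The interferon response list of 18 genes had a median of 2.90 (2.79 to 3.09) at day 3, with 17 members at least 2-fold higher, and 1.47, 0.88, 0.47 and 0.65 at the later days. Ifit3, an interferon-induced antiviral gene, was 10.5-fold (8.67 to 12.7) higher at day 3 and Isg15, a ubiquitin-like modifier, 9.75-fold (7.54 to 12.8). The inflammatory cytokine list had medians of 1.23 at day 3 and 0.23 at day 21. Each of these medians at day 3 lay at the percentile 100 of 10000 random lists matched on expression.

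The extracellular matrix list of 28 genes had a median of 0.32 (0.29 to 0.41) at day 3, 0.98 (0.94 to 1.02) at day 7, 1.16 (1.13 to 1.19) at day 10, 1.03 at day 14 and 1.14 (1.04 to 1.22) at day 21. There were 3, 13, 16, 15 and 16 members at least 2-fold higher at these days and none 2-fold lower. Fn1, which encodes fibronectin, was 4.97-fold (4.83 to 5.11) higher at day 10, Col1a1, a fibrillar collagen chain, 2.61-fold (2.56 to 2.66), and Eln, which encodes elastin, 4.78-fold (4.66 to 4.91) at day 14. Tnc, a matrix glycoprotein of wound tissue, was 47.0 CPM at day 0 and 524 CPM at day 10, and Ltbp2, a microfibril protein, 54.7 CPM and 692 CPM. Timp1, an inhibitor of matrix proteases, was highest early, with 2206 CPM at day 3 against 145 CPM at day 0. Cthrc1, a secreted protein of collagen-producing cells, was 0.279 CPM at day 0 and 115 CPM at day 14, Grem1, an antagonist of bone morphogenetic proteins, 0.149 CPM at day 0 and 241 CPM at day 21, and Thbs4, a matrix thrombospondin, 0.0186 CPM and 142 CPM. Chl1, a cell adhesion molecule, was 0.0743 CPM at day 0 and 112 CPM at day 10. Each of the last 4 had 15 or fewer reads at day 0, so only levels are given for them.

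Genes of the resting alveolar fibroblast were lower at every later day. Their list of 12 genes had medians of -0.97, -1.76 (-1.82 to -1.71), -1.21, -1.08 and -0.87 at days 3, 7, 10, 14 and 21, with 9 members at least 2-fold lower at day 7. Inmt, a methyltransferase of alveolar fibroblasts, was 12120 CPM at day 0 and 1048 CPM at day 7, 11.6-fold (11.3 to 11.9) lower, and Npnt, a basement membrane protein, was 5.55-fold (5.39 to 5.72) lower. Slc7a10, an amino acid transporter, was 38.2-fold (25.6 to 61.9) lower at day 7 and Tcf21, a transcription factor of the lineage, 3.44-fold (3.20 to 3.71). Igfbp3, which binds insulin-like growth factors, was 53.05-fold (42.2 to 67.3) lower at day 7, and Colq, which anchors acetylcholinesterase, was 117 CPM at day 0 and 1.26 CPM at day 7. Mapt, which encodes the microtubule protein tau, was 7.93-fold (6.58 to 9.59) lower at day 21 and Ppl, which encodes periplakin, 18.4-fold (12.5 to 27.0) lower at day 14. With 3 list members that are also markers of the class left out, the day 7 median was -1.64.

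The contractile list of 12 genes had medians in fibroblasts of -0.04 at day 3, 0.57 at day 7, 0.58 at day 10 and 0.30 at day 21. Acta2, the smooth muscle actin used to mark myofibroblasts, was 52.4 CPM at day 0 and 703 CPM at day 7, 8.01% of the level in smooth muscle cells and pericytes of that library. Cell cycle genes had medians of 1.80 at day 3, 1.92 (1.82 to 2.12) at day 7, 0.83 at day 10, 0.16 at day 14 and 1.04 at day 21. The p53 target list had medians between 0.44 and 0.65, and the MHC class II list lay between -0.36 and 0.55. Dissociation stress genes, which mark handling of the tissue, moved with the day as well, with medians of -0.38, -0.87, -0.87, -1.14 and -1.06, and Fosb, an immediate early gene of that list, was 2129 CPM at day 0 and 218 CPM at day 14. Spp1 reads were also widespread in cells that should lack the gene: after thinning to 2000 reads per cell, 33.1% of fibroblasts and 16.1% of B cells had an Spp1 read at day 7, and 30.2% and 28.3% at day 21, when the levels were 5449 CPM in fibroblasts and 260 CPM in B cells. The median log2 ratio of all genes with at least 10 reads in both libraries was -0.11 in fibroblasts at days 3 and 7.

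Matrix genes were also higher in the pool of smooth muscle cells and pericytes, the mix of which differed by day. Cluster 27, with Notch3 and Higd1b among its top genes, held 51.2%, 32.7% and 11.7% of it at days 0, 7 and 21, and cluster 19, with Acta2 and Myh11, 31.4%, 48.6% and 61.7%. The pool leaves out unnamed cluster 28, which also had Higd1b among its top genes. That cluster had 148, 41 and 21 cells at days 0, 7 and 21, against 124, 35 and 23 in cluster 27, so comparisons with day 0 depend on this. The extracellular matrix list medians of the pool were 0.38, 0.87 (0.79 to 0.98), 0.87, 0.51 and 0.52, and its contractile list stayed between 0.02 and 0.25. Acta2 was 8782 CPM at day 0 and 8775 CPM at day 7, a ratio of 0.999 (0.962 to 1.04). Fn1 was 4.68-fold (3.75 to 5.93) higher at day 7, Tnc 2.496-fold (1.85 to 3.41) and Col1a1 2.45-fold (2.21 to 2.71). The interferon list had medians of 2.07 at day 3, 1.11 at day 7 and -0.03 at day 10. The acute phase list was 0.57 at day 3, -0.71 at day 14 and 0.98 at day 21, and the resting alveolar fibroblast list lay between -0.65 and -0.41. Cell cycle genes were 1.44 at day 3 and 0.82 at day 21, p53 targets 0.04 to 0.48, and inflammatory genes 0.61 at day 7 and -0.40 at day 10. MHC class II genes of antigen-presenting cells were 0.14 at day 3 and 2.54 (2.22 to 3.02) at day 21. In NK cells this list was 3.53 (2.72 to 4.29) at day 21 against 37 cells of day 0. Free RNA was not separated from expression in either class. Stress genes had medians of -0.89 at day 14 and 0.01 at day 21, and the median over all genes was -0.14 at day 3.

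**Figure D2:**
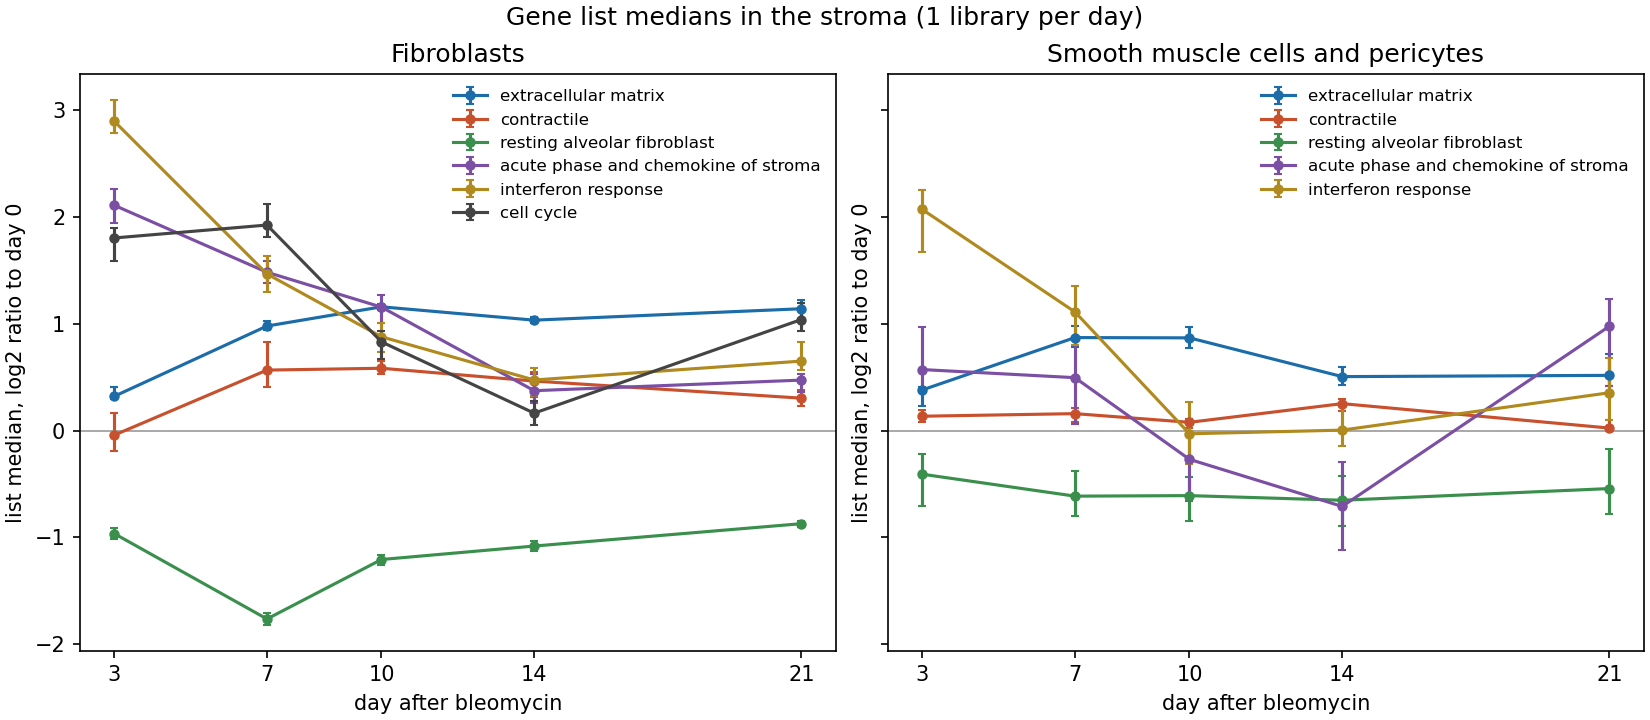
Median log2 ratio to day 0 of fixed gene lists against the day after bleomycin, in fibroblasts (left) and in smooth muscle cells and pericytes (right), with 1 library per day and bars for the 95% counting interval of the median. In fibroblasts the interferon and acute phase lists are highest at day 3, the extracellular matrix list stays near 1 from day 7 on, and the resting alveolar fibroblast list is below 0 at every day and lowest at day 7 with -1.76.

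The alveolar macrophage pool had higher levels of lipid-associated and profibrotic genes at each later day, and lower levels of resident genes. Cluster 34 held 93.9% of the pool at day 0, and cluster 6 held 95.2% at day 21. A different mix of these macrophages was not separated here from a difference within them. Spp1 was 748 CPM at day 0 and 17265 CPM at day 21, 23.1-fold (21.8 to 24.5) higher. Cd63, a lysosomal membrane protein, was 16.6-fold (13.9 to 19.9) higher at day 21, Igf1, a growth factor, 17.4-fold (12.6 to 24.3), Mfge8, a bridge to apoptotic cells, 25.4-fold (16.7 to 39.6) and Trem2, a lipid receptor, 10.4-fold (8.15 to 13.4). The list of 16 genes had medians of 1.20 (1.12 to 1.26), 1.33, 1.39, 1.75 and 1.86 (1.63 to 2.08) at days 3, 7, 10, 14 and 21, with 9, 10, 11, 10 and 11 members at least 2-fold higher and none 2-fold lower. Fabp5, a fatty acid carrier, was 325 CPM at day 0 and 1889 CPM at day 21. Arg1, which breaks down arginine, had a single read at day 0 (0.0418 CPM) and was 658 CPM at day 7 and 50.0 CPM at day 21, and Mmp12, an elastase, was 4.68 CPM at day 0 and 156 CPM at day 10. S100a4, a calcium-binding protein of motile cells, was 37.4-fold (22.8 to 67.6) higher at day 10, and Fam20c, a kinase of secreted proteins, was 1.05 CPM at day 0 and 100 CPM at day 10.

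The resident alveolar macrophage list of 15 genes had medians of -0.74, -0.81, -0.71, -0.97 and -0.72. Of its members, 10 are markers of the class, and without them the day 14 median was -0.06. Fabp1, a fatty acid binding protein, was 20.9-fold (15.8 to 28.3) lower at day 7, Krt79, a keratin, 20.9-fold (17.2 to 25.7) lower at day 14, Siglecf, a sialic acid receptor, 3.02-fold (2.71 to 3.38) lower and Pparg, the nuclear receptor that drives this cell type, 2.00-fold (1.74 to 2.29) lower. Epcam, an adhesion molecule, was 177 CPM at day 0 and 5.77 CPM at day 7. Ccl2, a monocyte attractant, was 24.1-fold (18.8 to 31.2) lower at day 10, and Ear10, a ribonuclease, 6.87-fold (5.25 to 9.07) lower at day 3. The interferon list had a median of 2.41 (2.25 to 2.65) at day 3 and 0.44 to 0.97 later. Irf7, a regulator of type I interferon, was 2.88 CPM at day 0 and 301 CPM at day 3. The p53 target list was 0.99 at day 3, and the MHC class II list 2.27 (2.19 to 2.36) at day 10 and 1.94 at day 21. Alternative activation genes had medians of 0.13 to 0.49, inflammatory genes -0.04 to 0.29 and cell cycle genes -0.02 to 0.78. Mmp9, a neutrophil protease, was 142 CPM at day 3 and under 1 CPM at the other days, and C1qa, a complement gene of other macrophages, was 0.585 CPM at day 0 and 172 CPM at day 7. Stress genes had medians between -0.86 and -0.23, and the median over all genes was -0.33 at day 21.

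Interstitial or monocyte-derived macrophages were compared with day 3, because day 0 held 29 of them, a choice made after the cell numbers were seen. Spp1 was 1610 CPM at day 3, 11418 CPM at day 7 and 23498 CPM at day 21, 14.6-fold (14.0 to 15.3) higher than at day 3. Gpnmb, a lysosomal glycoprotein, was 11.4-fold (9.50 to 13.7) higher at day 21, Mfge8 68.1-fold (44.2 to 107), and Atp6v0d2, a proton pump subunit, 37.7-fold (26.1 to 55.4). Ctsk, a collagen-degrading protease, was 8.84 CPM at day 3 and 456 CPM at day 21, and Ear2, a ribonuclease, 43.3 CPM at day 3 and 885 CPM at day 10. The lipid-associated list had medians of 1.01, 1.15, 1.79 (1.73 to 1.85) and 1.79 at days 7, 10, 14 and 21, with 8, 8, 12 and 12 of 16 members at least 2-fold higher. Without the 4 members that are markers of the class the day 14 median was 1.496. Arg1 was highest at day 7 with 1565 CPM against 492 CPM at day 3. Cluster 12 held 57.1% of the class at day 3. Cluster 5, with Gpnmb, Arg1, Mmp12, Trem2 and Spp1 among its top genes, held 33.6% at day 3, 67.9% at day 7 and 53.8% at day 21. Cluster 44, with Cd163, Folr2 and Cd209f among its top genes, held 34.5%, 9.24%, 4.28% and 4.87% at days 0, 3, 7 and 21. A different mix of these macrophages was not separated here from a difference within them.

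Other genes of these macrophages were lower than at day 3. The interferon list had medians of -1.26, -1.43, -1.38 and -1.30, with 12 or 13 of 18 members at least 2-fold lower. The alternative activation list was -0.18 at day 7 and -1.18 (-1.36 to -1.05) at day 21. Cd163, a scavenger receptor for haemoglobin, was 771 CPM at day 0, 189 CPM at day 3 and 21.1 CPM at day 21. Cd209f, a lectin, was 31.9-fold (22.1 to 46.1) lower at day 7, Mgl2, a galactose lectin, 7.83-fold (6.84 to 8.97) lower, and Ccr2 3.98-fold (3.65 to 4.35) lower at day 21. Cxcl13 was 306 CPM at day 3 and 4.77 CPM at day 7. Ms4a4c, a monocyte gene, was 34.2-fold (23.0 to 52.0) lower at day 21. The resident alveolar macrophage list was higher, with medians of 0.69 at day 7 and 1.99 at day 21, while Marco, a scavenger receptor of that list, was 13.04 CPM at day 3 and 1.24 CPM at day 21. MHC class II genes had medians of -1.35 at day 7, 0.14 at day 10 and -0.65 at day 21, and with CPM averaged over cells the day 21 value was 0.09. Inflammatory, p53 and cell cycle lists were below 0 at each of these days, between -0.92 and -0.11, and stress genes lay between -0.21 and 0.20. Several medians were no longer below 0 against the 29 cells of day 0: there the medians at days 7, 10, 14 and 21 were 0.14, 0.17, 0.13 and 0.27 for interferon genes, 0.86, 0.39, 0.10 and 0.31 for cell cycle genes and 0.13, 0.39, 0.25 and 0.33 for p53 targets. The interferon intervals all included 0 (-0.03 to 0.96, -0.14 to 0.85, -0.09 to 0.89 and -0.11 to 0.67), as did that of p53 targets at day 7 (-0.01 to 0.90). These values therefore show no clear direction against day 0. Against the same day 0 cells, MHC class II genes lay between -2.79 and -1.11 and stress genes between -1.19 and -0.51, while the lipid-associated list was 2.51, 2.60, 3.10 and 3.30. The median over all genes was -0.22 at day 7 and -0.36 at day 21. Slpi, a protease inhibitor, was 2.44 CPM at day 3 and 202 CPM at day 21, and its log2 ratio was -0.04 when doublets were kept. In classical monocytes, also against day 3, the interferon list had medians of -0.63 at day 7 and -1.49 at day 14. Against the 43 classical monocytes of day 0 these were 0.78 and -0.11, so the day 7 direction turned with the reference. At days 10 and 21 the medians against day 0 were 0.51 and 0.83.

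**Figure D3:**
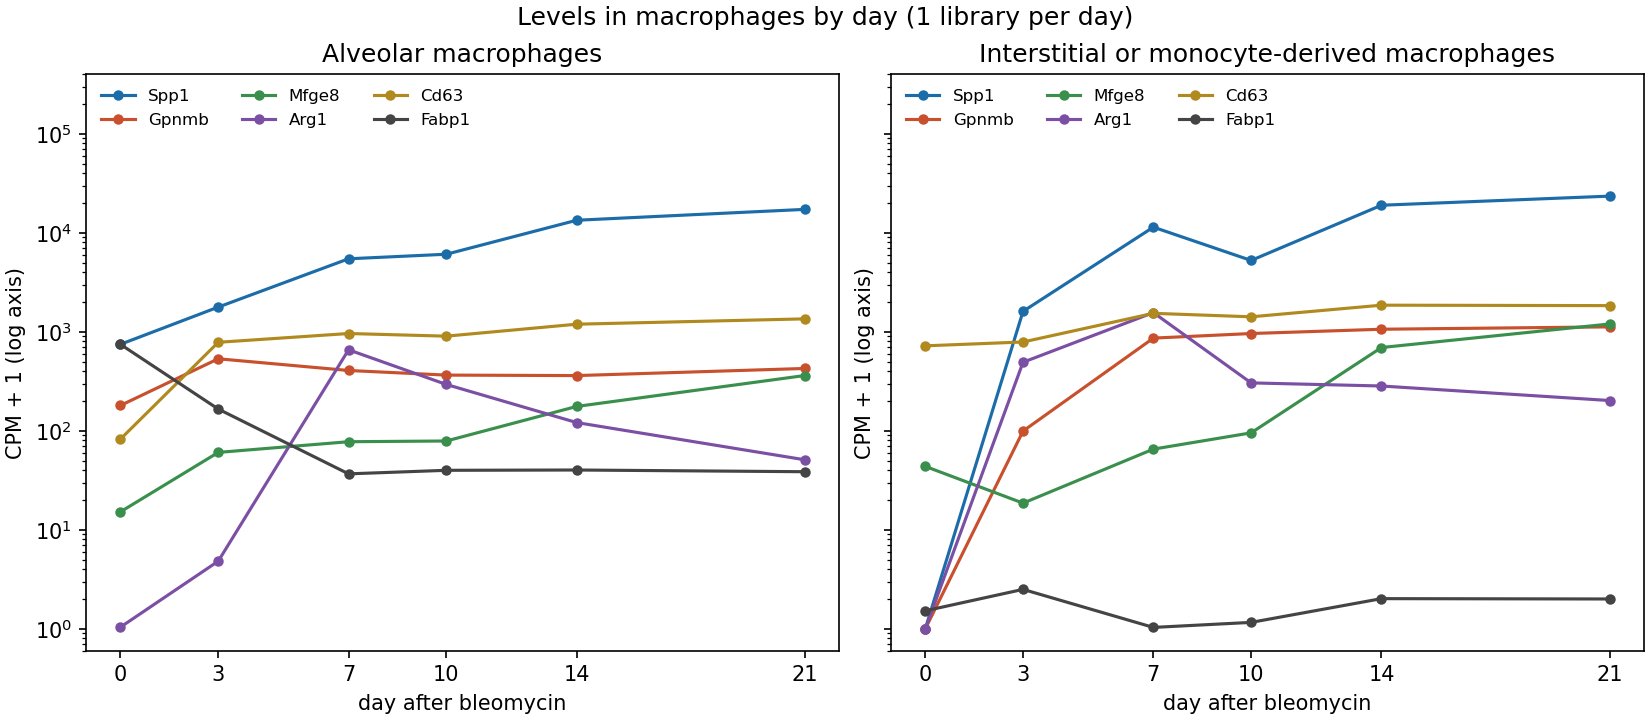
Summed read level (CPM plus 1, log axis) of 6 genes against the day after bleomycin in alveolar macrophages (left) and interstitial or monocyte-derived macrophages (right), 1 point per library and no error bars. Spp1 is highest at day 21 in both classes, at 17265 CPM and 23498 CPM, Arg1 is highest at day 7, and Fabp1 is highest at day 0 in alveolar macrophages.

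In AT2 cells, RNA of p53 target genes was higher than at day 0, most of all at day 3 among the days compared, while p53 activity itself was not measured. Cdkn1a, the p21 inhibitor of the cell cycle, was 131 CPM at day 0 and 1246 CPM at day 3, 9.50-fold (8.61 to 10.5) higher. Ccng1, a cyclin induced by p53, was 15.3-fold (12.8 to 18.3) higher, Phlda3, an inhibitor of Akt signalling, 45.6-fold (27.8 to 80.6), and Bax, a mediator of apoptosis, 4.97-fold (4.01 to 6.15). The list of 16 p53 targets had medians of 2.03 (1.81 to 2.20), 0.72, 0.56 and 0.72 at days 3, 10, 14 and 21, with 13 members at least 2-fold higher at day 3. Day 7 is left out because it held 24 AT2 cells. The interferon list was 1.64 (1.43 to 1.93) at day 3 and 0.14 to 0.33 later. Lcn2 was 927 CPM at day 0, 10689 CPM at day 3 and 4407 CPM at day 21, and Ifi27l2a, an interferon-induced gene, 12.9 CPM at day 0 and 1258 CPM at day 3. Retnla, a secreted resistin-like protein of type 2 immunity, was 35.8 CPM at day 0 and 1468 CPM at day 3, and Orm1, an acute phase protein, 0.422 CPM and 86.5 CPM. Itm2a, a membrane protein, was 16.2-fold (11.4 to 24.1) higher at day 21, Slc26a4, an anion exchanger, 11.01-fold (7.57 to 16.0) at day 10 and Sprr1a, a marker of the transitional state, 12.98-fold (9.30 to 18.6) at day 14.

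The transitional state list had medians in AT2 cells of 0.81, 0.70, 0.65 and 0.33, with 4 to 7 of 16 members at least 2-fold higher. The surfactant and lamellar body list lay between -0.27 and -0.11, and 9 of its 12 members are markers of the class. Without those members the medians at days 10, 14 and 21 turned to 0.20, 0.07 and 0.20. Sftpc, surfactant protein C, was 185293 CPM at day 0, 108889 CPM at day 3 and 174967 CPM at day 21, and Sftpb, surfactant protein B, 23910 CPM, 23324 CPM and 18018 CPM. Pon1, an esterase, was 28.7-fold (12.9 to 94.3) lower at day 21, and Bex2 was 7.81-fold (6.20 to 9.87) lower at day 3. Atf3, a stress-induced transcription factor, was 13.9-fold (11.3 to 17.1) lower at day 14 and Socs3, a brake on cytokine signalling, 8.01-fold (6.98 to 9.22) lower at day 21. The stress list as a whole had medians of -0.65, -1.09, -1.67 and -0.88. Cell cycle genes were -0.37 at day 3 and 1.21 at day 10, and MHC class II genes -0.05 at day 3 and 0.76 at day 21. Inflammatory genes lay between -0.04 and 0.07. The median over all genes was 0.15 at day 3.

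AT1 cells, which had at least 50 cells at days 0, 3, 14 and 21, had p53 list medians of 2.12 (1.73 to 2.35), 0.75 and 0.92, with 14 of 16 members at least 2-fold higher at day 3. Cdkn1a was 14.5-fold (12.9 to 16.4) higher at day 3 and Ccng1 10.6-fold (8.74 to 13.05). Their transitional list was 1.04, 1.002 and 1.15 and Krt8, a simple epithelial keratin, was 413 CPM at day 0 and 913 CPM at day 21. Ager, the receptor that marks AT1 cells, was 8735 CPM at day 0 and 8802 CPM at day 3, a ratio of 1.01 (0.979 to 1.04). The surfactant list was -1.28, -0.06 and -0.29, the interferon list 1.30, 0.11 and 0.19, the inflammatory list -0.08, -0.51 and -0.33, the cell cycle list 0.20, 0.09 and 1.65 and the MHC class II list -0.79, 1.63 and 1.66. Free RNA was not separated from the surfactant and MHC class II values. In B cells, Sftpc was 640 CPM at day 0 and 175 CPM at day 3. Stress genes were -0.90, -1.53 and -1.11. In the transitional epithelium itself, Cdkn1a was 5407 CPM at day 3, 2844 CPM at day 7 and 2179 CPM at day 21, while Nupr1, a stress-induced chromatin protein, was 566 CPM at day 3 and 3313 CPM at day 21. Clu, a chaperone, was 1467 CPM at day 3 and 3649 CPM at day 21, and Sprr1a 2413 CPM and 468 CPM. Days 10, 14 and 21 held 35, 24 and 49 transitional cells.

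In general capillary endothelium, interferon genes were higher at day 3, and the endothelial activation list had a median above 0 at every day from day 3 on, with members going both ways. Its interferon list had medians of 1.61 (1.44 to 1.74) at day 3 with 14 of 18 members at least 2-fold higher, then -0.64, -0.06, -0.41 and -0.14. Cxcl9, a chemokine for T cells, was 0.674 CPM at day 0 and 50.2 CPM at day 3. Lrg1, a secreted promoter of angiogenesis, was 29.2 CPM at day 0 and 1308 CPM at day 7, 44.9-fold (33.1 to 63.7) higher, and 643 CPM at day 21. The endothelial activation list of 17 genes had medians of 0.44, 0.68 (0.51 to 1.45), 0.71 (0.38 to 0.87), 0.53 and 0.40. The day 10 value was 1.14 with a pseudocount of 1 CPM and 0.37 with CPM averaged over cells. There were 8 members at least 2-fold higher and 4 at least 2-fold lower at day 7. Vwf, which encodes von Willebrand factor, was 326 CPM at day 0 and 1398 CPM at day 7, Sparcl1, a matricellular protein, 397 CPM and 2085 CPM, and Ntrk2, a neurotrophin receptor, 53.4 CPM and 208 CPM. Plvap, the diaphragm protein of capillary pores, was 1.37-fold (1.30 to 1.44) lower at day 10.

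Several further capillary genes had large ratios. Ankrd37, a target of the hypoxia response, was 24.3-fold (15.7 to 38.1) higher at day 7, Clca3a1, a chloride channel regulator, 24.7-fold (14.3 to 50.2), Lama1, a laminin chain, 26.1-fold (12.6 to 66.1) at day 10 and Tiam1, an activator of Rac, 21.5-fold (12.5 to 42.7) at day 14. Ch25h, which makes 25-hydroxycholesterol, was 0.0962 CPM at day 0 and 114 CPM at day 7. Zbtb16, a transcription factor, was 10.6-fold (7.07 to 16.6) higher at day 3 and Dbp, an output gene of the circadian clock, 15.6-fold (8.49 to 35.9) at day 21. Npr3, the clearance receptor of natriuretic peptides, was 23.6-fold (16.2 to 35.2) lower at day 7, and Esm1, a secreted proteoglycan of tip cells, was 41.2 CPM at day 0 and 0.765 CPM at day 7. Alas2, the erythroid enzyme of haem synthesis, was 27.3 CPM at day 0 and had no read at day 3, but its day 14 log2 ratio was 0.61 when doublets were kept. Cell cycle genes had medians of 0.29, -0.64, 1.90 (1.59 to 2.00), 1.38 and 0.98. MHC class II genes were 0.70 at day 3 and 0.90 at day 21, p53 targets 0.61 at day 3 and 0.22 at day 21, inflammatory genes 0.48 at day 3 and 0.19 at day 21, and stress genes between -0.52 and 0.01. The median over all genes was -0.12 at day 7. Cluster 1 held 86.6% of the class at day 0 and 68.8% at day 21, cluster 20 held 65.8% at day 3, and cluster 4 held 48.9% at day 10 and 49.8% at day 14. In aerocytes, the capillary cells of gas exchange, the interferon list was 1.26 at day 3 and the activation list 1.30 at day 7.

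The T cell pool had a higher median of regulatory T cell genes at each later day, highest at day 10, and more of its cells lay in a cluster with these genes. Cluster 13, with Foxp3, Ctla4 and Ikzf2 among its top genes, held 11.9%, 14.3%, 26.9%, 38.2%, 22.5% and 28.3% of T cells at days 0, 3, 7, 10, 14 and 21, and a different mix of T cells was not separated here from a difference within them. Foxp3, which defines regulatory T cells, was 41.7 CPM at day 0 and 259 CPM at day 10, 6.22-fold (3.998 to 9.93) higher. Il1rl1, the receptor for Il33, was 28.2-fold (10.2 to 147) higher at day 10, Tnfrsf9, a costimulatory receptor, 22.6-fold (10.5 to 76.4), Ikzf2, which encodes Helios, 4.28-fold (3.03 to 6.38) and Ctla4, an inhibitory receptor, 3.49-fold (2.89 to 4.21). The regulatory list of 12 genes had medians of 0.59 (0.30 to 0.79), 1.54, 2.44 (2.13 to 2.78), 1.60 and 1.29 at days 3, 7, 10, 14 and 21, with 11 members at least 2-fold higher at day 10; 3 of the members are markers of the class. Il10, an anti-inflammatory cytokine, had no read at day 0 and 39.6 CPM at day 10. The effector list of 14 genes had medians of 0.46 to 0.75, and 0.95 at day 3 and 0.96 at day 10 with CPM averaged over cells. The interferon list was 1.49 (0.98 to 1.69) at day 3 and -0.02 to 0.21 later, with Cxcl10, a chemokine for T cells, at 7.16 CPM at day 0 and 149 CPM at day 3.

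Penk, which encodes proenkephalin, had no read at day 0 and 79.7 CPM at day 7, and Ccl1, a chemokine for Ccr8, 0 reads at day 0 and 293 CPM at day 21. Xcl1, a chemokine for dendritic cells, was 13.4-fold (6.02 to 31.7) higher at day 21. Gzma, a granzyme, was 42.4-fold (14.1 to 219) lower at day 10, Ccr9, a homing receptor of the gut, 5.57-fold (2.88 to 10.9) lower at day 7 and Cnn3, a calponin, 8.27-fold (3.98 to 18.9) lower at day 21. The cell cycle list was -1.06, -0.38, -0.04, -1.75 and -0.64, with 17 of 20 members at least 2-fold lower at day 14, but with CPM averaged over cells it was -0.38, 0.14, 0.71, -0.48 and 0.04. Hmmr, a mitotic spindle gene, was 47.2 CPM at day 0 and 0.118 CPM at day 14. Inflammatory genes had medians of 0.24 to 0.57, p53 targets 0.08 to 0.19, and stress genes 0.09, 0.13, 0.17, 0.43 and 0.92 (0.63 to 1.08). MHC class II genes of antigen-presenting cells were also higher, with medians of 1.10 to 2.82, and Cd74 at day 7 was 186 CPM, 0.719% of the highest class. Day 0 held 177 T cells, of which cluster 10 held 44.1%, and cluster 9 held 43.0% of the day 3 T cells.

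Cycling cells were counted after each cell was thinned to 2000 reads, as cells with at least 3 of 20 cell cycle genes. None of 729 fibroblasts met this at day 0 (0 to 0.505%), against 8.17% (5.93 to 10.9) at day 7 and 1.43% (0.786 to 2.39) at day 21. The day 0 share was 1.37% with at least 2 genes and 1.65% with 9000 reads per cell. General capillary cells had 1.32% (0.573 to 2.59) at day 0, 0.714% at day 7, 7.85% (5.79 to 10.4) at day 10 and 5.04% (3.70 to 6.68) at day 14, or 2.81%, 3.93%, 14.7% and 10.5% with 9000 reads per cell. Interstitial or monocyte-derived macrophages had 13.4% (7.88 to 20.9) at day 3 and 1.39% (0.513 to 3.00) at day 21. The gap depended on depth: the shares were 18.5% and 8.35% with 9000 reads per cell, and 56.3% and 57.1% in unthinned cells. Cluster 35, a cluster of cycling cells whose markers did not decide between the 2 macrophage classes, was left out of each, with 15 cells at day 3, 109 at day 7 and 60 at day 21. Among all cells without a name, 111 of 235 cycled at day 7 and 59 of 112 at day 21. Alveolar macrophages had 2.42% (0.664 to 6.09) at day 0 and 7.5% (2.80 to 15.6) at day 7. T cells had 4.52% (1.97 to 8.71, 8 of 177 cells) at day 0, 6.93% (4.82 to 9.60) at day 10 and 1.97% (1.08 to 3.28) at day 14. With 9000 reads per cell these were 7.34%, 14.3% and 6.60%, and with at least 2 genes 8.47%, 14.5% and 6.32%, so days 0 and 14 differed little there. B cells, taken as the background, had 0.182% to 0.886%. No retained cell was too shallow for thinning. In unthinned cells the fibroblast shares were 12.5% at day 0 and 57.4% at day 7, the capillary shares 5.79% at day 0 and 23.4% at day 10, and the B cell shares 6.96% at day 0 and 8.92% at day 7.

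The last comparison asked which of 60 fixed ligand-receptor pairs were expressed by at least 10% of thinned cells of a sending and a receiving class. Such co-detection is of RNA and not of signalling. Over the 8 classes with at least 50 cells in every library, 25, 26, 28, 27, 25 and 26 pairs were detected at days 0, 3, 7, 10, 14 and 21, and 42, 49, 50, 49, 48 and 49 in unthinned cells. These were fibroblasts, smooth muscle cells and pericytes, general capillary, aerocyte and arterial or venous endothelium, alveolar macrophages, B cells and T cells. AT2 cells, interstitial or monocyte-derived macrophages and classical monocytes were left out. The number of combinations of pair, sender and receiver was 201, 214, 263, 281, 257 and 240. The 14 classes with at least 20 cells in every library gave 37, 36, 36, 38, 36 and 34 pairs. They included the 3 classes left out above and gave 563, 714, 857, 820, 813 and 736 combinations. Pair and combination counts below are for the 8 classes. When both genes also had to reach 10% of the level of the highest class, a rule added against free RNA after the data were seen, the combinations were 177, 166, 207, 207, 200 and 180. Spp1-Cd44, osteopontin and a receptor for it, was found in 12, 10, 35, 42, 32 and 40 combinations, and Fn1-Itga5, fibronectin and its integrin chain, in 6, 12, 20, 24, 24 and 12. Spp1 reads were in 28.3% of B cells at day 21, so many late Spp1-Cd44 senders lie near the background.

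Some pairs were found in few combinations. Osm-Osmr, oncostatin M and its receptor, had 1, 4, 4, 5, 3 and 2 combinations, and Osm was in 33.8% and Osmr in 0% of alveolar macrophages at day 7, while Osmr was in 23.3% of fibroblasts and 0.782% of B cells. Il1b-Il1r1, interleukin 1 beta and its receptor, had 0, 2, 2, 4, 2 and 1 combinations, with Il1b in 33.8% of alveolar macrophages and 0.782% of B cells at day 7 and Il1r1 in 9.47% of fibroblasts at day 0 and 20.8% at day 3. Hbegf-Egfr, an epidermal growth factor ligand and its receptor, was detected only at days 3, 7 and 10 in this set of classes. Tgfb1-Tgfbr2, transforming growth factor beta and its receptor, was found in 48, 40, 64, 56, 64 and 48 combinations. Ccl2, the ligand of Ccr2, was in 34.5% of interstitial or monocyte-derived macrophages at day 0, 35.4% at day 7 and 19.5% at day 21, and in 35.6% of classical monocytes at day 3, against 0.463% of B cells at day 3.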

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

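Of the tests below, the one on a handling difference was written only after its result was seen, and the others were written before. With 1 library per day, none of the differences between classes or days was tested.

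Several gene lists differed between classes or days in direction. The cell cycle list was higher in fibroblasts at day 7 (1.92) and lower in T cells at day 14 (-1.75, or -0.48 with CPM averaged over cells). The dissociation stress list was lower at day 14 in fibroblasts (-1.14), alveolar macrophages (-0.86) and AT2 cells (-1.67), and higher in T cells at day 21 (0.92). The difference was not tested in any of these.

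Clusters without a name were left out of the gene comparisons by class. Cluster 30, with Mmp12, Ccl17 and Mgl2 among its top genes, was 0.103% of cells at day 0 and 3.35% (2.86 to 3.90) at day 10. Cluster 35, with cell cycle genes, was 0.205% and, at day 7, 2.78% (2.28 to 3.34). Cluster 51 was 0.0513% at day 0 and 0.368% (0.231 to 0.557) at day 14. The difference was not tested.

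At day 21 dissociation stress genes were lower in fibroblasts and AT2 cells and higher in T cells. The T cell median of 0.92 (0.63 to 1.08) is part of the pattern and tests nothing. Among classes outside the pattern, looked up afterwards, the median was 0.67 (0.39 to 0.81) in B cells and 1.21 (0.90 to 1.52) in nonclassical monocytes. As given above, the list was lower in AT1 cells and alveolar macrophages and little different in smooth muscle cells and pericytes. The classes did not all move the same way, which argues only against a handling difference that moves all cells of the library alike. Sampling of other fibroblast states would leave the list unchanged inside a cluster. Within the clusters with at least 30 cells at each day, the highest median was -0.53 (-0.60 to -0.48), with -1.05 in cluster 3. The list was thus lower inside every such cluster, although the interval of the highest median crosses the bound of 0.5 below 0 that was set beforehand. Cluster 22, with 378 fibroblasts at day 0 and 8 at day 21, and cluster 17, with 1 and 145, had too few cells for this test. It therefore cannot decide for the fibroblasts as a whole whether other states were sampled. A handling difference that acts on stromal and lymphoid cells in different ways may still explain the pattern, as may the day after bleomycin, and these cannot be separated because day and library are the same.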

How the results depend on the processing

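No paired analysis was possible because there was 1 library per day, and the replicate number 1 only names a sample. Directions of the shares, lists and genes held under most alternatives. For lists, 274 values kept within the counting interval with a pseudocount of 1 CPM and 87 moved, 279 and 81 with scaling by median of ratios, and 245 and 112 with CPM averaged over cells, while leaving out the filter on low counts moved 0 of 361. For shares, 146 stayed and 10 moved at resolution 2.5. The class per cell from markers moved 53 and left 103. Depth limits the cycling shares and pair counts, which are set by the thinning. For all values below, the cause was not tested.

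At resolution 0.8, interstitial or monocyte-derived macrophages were 17.6% at day 7 and T cells 10.7% at day 14. With at least 500 genes per cell, AT1 cells at day 7 were 0.229%. With class per cell from markers, general capillary cells at day 7 were 8.32%, interstitial or monocyte-derived macrophages 19.2%, classical monocytes at day 3 6.33% and T cells at day 14 10.7%. Without doublet removal, interstitial or monocyte-derived macrophages at day 7 were 18.3%, the extracellular matrix list in fibroblasts at day 10 was 1.12 and the lipid-associated list in interstitial or monocyte-derived macrophages at day 14 was 1.63, and signs turned for MHC class II in fibroblasts at day 10 (0.095), Slpi in interstitial or monocyte-derived macrophages at day 21 (-0.044) and Alas2 in general capillary cells at day 14 (0.61).

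With a pseudocount of 1 CPM, the p53 list in AT2 cells at day 3 was 2.24, the acute phase list in fibroblasts at day 3 was 2.46 and the activation list in general capillary cells at day 10 was 1.14. With scaling by median of ratios, the resting list in fibroblasts at day 7 was -1.65, extracellular matrix at day 10 was 1.23, the lipid-associated list was 2.17 in alveolar macrophages at day 21 and 2.06 in interstitial or monocyte-derived macrophages at day 14, and MHC class II in B cells at day 21 turned to 0.013. With CPM averaged over cells, these were -1.71 for resting, 1.33 for extracellular matrix, 0.37 for capillary activation and 1.36 for the lipid-associated list in interstitial or monocyte-derived macrophages. Signs turned for MHC class II in fibroblasts at day 14 (0.31) and in interstitial or monocyte-derived macrophages at day 21 (0.089). They also turned for the cell cycle list in T cells at days 7 (0.14), 10 (from a value near 0, as given above) and 21 (0.042).

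The pairs detected in unthinned cells were 42, 49, 50, 49, 48 and 49 by day, and with a 20% threshold 17 at day 3, 15 at day 7 and 15 at day 21. With at least 2 cell cycle genes, cycling shares were 11.6% in fibroblasts at day 7 and 13.6% in general capillary cells at day 10, beside 5.32% of B cells at each of these days and 1.37% of fibroblasts at day 0. Unthinned they were 57.4% and 23.4%, and 56.3% in interstitial or monocyte-derived macrophages at day 3, where day 21 had 57.1%.

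Alternatives chosen after seeing the data gave these values. With the highest 5% of doublet scores removed in every library, AT1 cells at day 7 were 0.132% and interstitial or monocyte-derived macrophages 17.1%. With list members that are not markers of the class, the resting list in fibroblasts at day 7 was -1.64, capillary activation at day 10 was 0.87, the resident list in alveolar macrophages at day 14 was -0.060, the lipid-associated list in interstitial or monocyte-derived macrophages at day 14 was 1.496, and the surfactant list in AT2 cells turned to 0.20, 0.070 and 0.20 at days 10, 14 and 21. Thinned to 9000 reads, 40 pairs were detected at day 3, and the cycling shares were 12.6% in fibroblasts at day 7 and 14.7% in general capillary cells at day 10, beside 2.35% and 3.55% of B cells.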

Other observations

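Clock genes in capillary endothelium differed between days 0 and 21. Dbp was 6.79 CPM at day 0 and 106 CPM at day 21. Clock genes that peak with Dbp had a median log2 ratio of 0.74 (0.49 to 0.98), with Tef at 29.1 and 107 CPM, and genes of the opposite phase had -0.63 (-1.15 to -0.31), with Arntl at 24.9 and 8.07 CPM. Another time of day at collection fits these medians and could explain the ratio of Dbp. Both intervals, however, cross the bounds of 0.5 above and 0.5 below 0 that were set beforehand. For an effect confined to general capillary cells, the median Dbp log2 ratio over the other classes was 1.03, but it ranged from -0.66 to 2.71 and decides nothing alone. Single classes, looked up afterwards, argue against such an effect: Dbp was 20.1 and 142 CPM in smooth muscle cells and pericytes, a ratio between 4.03 and 14.4, and 16.8 and 138 CPM in arterial or venous endothelium, a ratio between 3.81 and 18.4. The time of collection is not given in the sources used here, and a shift of the clock by the treatment stays open.

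Zbtb16 in general capillary cells was 18.0 CPM at day 0 and 191 CPM at day 3. Targets of the glucocorticoid receptor had a median of 1.397 (1.19 to 1.63) there, with Fkbp5 at 7.31 and 56.8 CPM and Mt2 at 4.62 and 224 CPM, while Sgk1 was lower, at 272 and 171 CPM. A glucocorticoid response at day 3 fits these values. A cluster of capillary cells seen mostly at day 3 is argued against, because within the largest capillary cluster the Zbtb16 log2 ratio was 2.91 (2.51 to 4.002). The same targets had medians of 1.38 in fibroblasts and 1.77 in AT1 cells at day 3, and in fibroblasts Mt1 was 441 CPM at day 0 and 5143 CPM at day 3. Metallothioneins such as Mt1 and Mt2 also respond to metals and inflammation, so a stress response without the hormone may contribute.

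Unnamed cluster 28 made up 3.79%, 1.95%, 1.04%, 0.910%, 0.402% and 0.320% of cells at days 0, 3, 7, 10, 14 and 21. Smooth muscle cells and pericytes were its best class, with Cox4i2 and Higd1b among its top genes. It got no name because markers of aerocyte endothelium were too many beside these. Its cells had a median of 2.55 times the reads of their library's median cell, and whether they were doublets was not tested.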
